A study of Mus musculus with 32 samples.

How the data were processed

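The series holds 32 arrays of hippocampal RNA from untreated mice of 8 inbred strains on an Affymetrix mouse array (U74Av2). Per the series design, RNA was pooled within each strain (6 mice, 1 pool), 1 cDNA was made from each pool, cRNA was made from it in 2 preparations, and each preparation was hybridised to 2 arrays. Arrays numbered 1 and 2 carry the first preparation and arrays 3 and 4 the second. Strain and number were read from the sample titles, which also end in a day of 6 different days. The deposited values are intensities: 1 linear signal per probe set and array, made with MAS5 per the submitters' processing notes, which give no version. The scaling target and detection calls are not given in the sources used here. On every array the mean of the deposited intensity, with 2% trimmed from each end, lay between 100.05 and 100.07, so the arrays were taken as already scaled. Scanner images and probe-level values were not analysed here.

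Gene names came from the platform's annotation table, which listed 11251 probe sets, 10855 with 1 gene symbol and 396 with several. A further 1193 non-control probe sets had no entry and stayed unnamed here, and no gene was named from a probe set with several symbols. Through their Entrez numbers 10839 probe sets matched a RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols, and that table was used for names and for which genes are neighbours. No coordinates are given. Probe sets whose suffix is _s_at, _f_at, _i_at, _r_at or _g_at can read more than 1 transcript, and their gene assignment is uncertain. Of 12488 probe sets, 66 controls were left out. Signals under 1 were set to 1 (2.14% of all values) and log2 was taken. The 60% of probe sets with the highest mean were tested, 7453 in number, which put the limit at a mean signal of 21.3. Of these, 6743 had 1 symbol, for 5660 genes.

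The unit of replication was the cRNA preparation: the 2 arrays of a preparation were averaged, which gave 16 values, and 1 linear model with 8 strain means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend on mean signal, 8 residual degrees of freedom). A moderated F-test compared the 8 strains, contrasts set each strain against the mean of the other 7, and 28 contrasts compared pairs. P-values were adjusted by Benjamini-Hochberg within each test, with a threshold of 0.05, and a difference of 2-fold is 1 on the log2 scale. Because a strain is 1 pool, p-values measure the spread of preparations and hybridisations and not that between animals. Variance shares came from nested mean squares over the 32 arrays. Gene lists were tested with a two-sided Fisher's exact test for called genes, with the probe set of highest mean signal standing for a gene, and with limma's camera at a correlation of 0.01, repeated with the correlation estimated from the data.

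The lists, tests, filter, alternatives and the rule for named genes were fixed before the data were examined. The rule named 5 groups of genes. These were the 25 genes with the widest range across strains past the F-test, and for each strain the 3 highest and 3 lowest past its test with both preparations outside all 14 other values. Up to 4 genes of each list, the 10 genes with the largest difference between C57BL/6J and DBA/2J, and a set of candidates with sex-linked checks completed it. A gene with no single symbol was not named. Genes named outside this rule are marked as chosen after their values were seen.

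The array numbers pair the samples across strains, because the series design states that they mark the preparation. In the data, the difference between preparations 1 and 2 correlated across probe sets for all 28 pairs of strains, with r from 0.109 to 0.557 and a median of 0.385. Pairs with BALB/cByJ had r from 0.109 to 0.244, and all other pairs 0.301 or more. A block is thus least well founded for BALB/cByJ, but the pairing was seen in the other strains. The fit with the preparation number as a block is therefore printed beside each count that it moved. No pair of arrays held identical values. Alternatives covered normalization, the filter, the offset before log2 (16 or 64), the block, single arrays as units with and without the day, the variance trend, and leaving out each array and each preparation. Others, added after the data were seen, concerned the sense-strand control probe sets and array 2 of FVB/NJ.

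The fit was tested on simulated data of 7453 probe sets with the observed means and variances and 200 changed in C57BL/6J. Of 100 changed by 1 on the log2 scale, 72% were recovered in the contrast of C57BL/6J against the rest, and of 100 changed by 2, 92%. The F-test recovered 23% and 77%. Of the unchanged probe sets 16 were called in the contrast and 6 by the F-test, and no call had the wrong sign. For camera on the same simulated values, 3% of 200 random lists of 25 probe sets had an unadjusted p under 0.05 in the contrast of A/J. The simulated probe sets were independent of each other and had no shift shared by preparations. This therefore does not test camera under the correlation of the real data. Figures were drawn with matplotlib 3.10.9.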

Results

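Gene expression in the hippocampus was measured in 8 inbred mouse strains with 32 arrays, 4 for each strain. The strains were SvImJ, A/J, BALB/cByJ, C3H/HeJ, C57BL/6J, DBA/2J, FVB/NJ and SJL/J. SvImJ is only the last part of that strain's name, which the sample titles and the figures give in full. The mice received no treatment, and the question the design poses is which transcripts differ in level between strains that also differ in behaviour. Each strain was represented by 1 pool of RNA from 6 mice. Its cDNA was turned into cRNA in 2 separate preparations, and each preparation was hybridised to 2 arrays. The 4 arrays of a strain are therefore technical replicates, every p-value below measures technical spread, and no error between animals can be given. Values are log2 of the deposited signal, means and SDs are over the 2 preparations of a strain (n = 2), and the number of arrays limits their precision. Of 12422 non-control probe sets, the 7453 with the highest mean signal were tested, and they stood for 5660 named genes. The median signal of an array lay between 29.4 and 43.7. The table carried no detection calls, so levels near the low end are signals and not evidence of a transcript.

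Strain was a minor part of the spread of a typical probe set. Over all tested probe sets the median share of variance was 6.73% for strain, 20.9% for cRNA preparation and 58.3% for array. Among the 341 probe sets past the F-test across strains the median share of strain was 74%, which the selection by that test itself raises. Across probe sets, arrays of the same preparation had a median correlation of 0.950, arrays of the same strain but different preparations 0.927, and arrays of different strains 0.920. Control probe sets that read the sense strand of actin and Gapdh were high on 11 arrays (log2 6.95 to 7.84) and low on the other 21 (4.91 to 5.64). The 11 were all 4 arrays of BALB/cByJ, arrays 1 and 2 of A/J, C3H/HeJ and SJL/J, and array 1 of FVB/NJ.

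**Figure D1:**
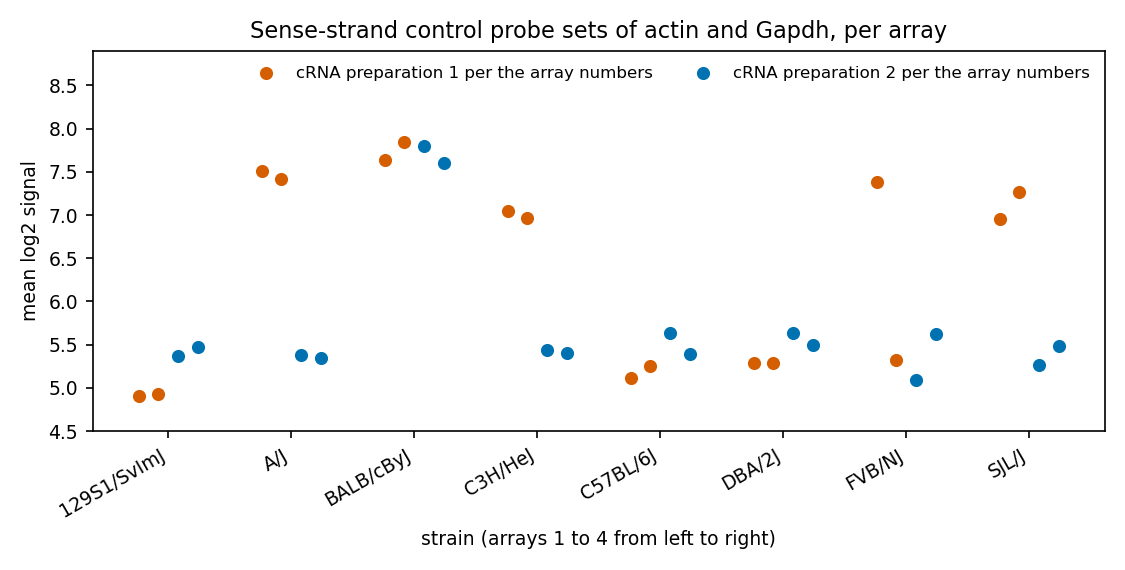
Mean log2 signal of the 6 sense-strand control probe sets of actin and Gapdh on each of the 32 arrays, with strains along the horizontal axis and colours for the cRNA preparation that the array number gives. The 11 high arrays lay between 6.95 and 7.84 and included all 4 of BALB/cByJ.

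The transcripts with the widest range across strains were mostly high in some strains and near the bottom of the signal range in others. 1 of 3 probe sets for Pdxdc1, a decarboxylase-domain protein, read 8.22 ± 0.08 in DBA/2J, 8.15 ± 0.24 in C3H/HeJ and 7.88 ± 0.31 in BALB/cByJ, and between 2.94 and 3.61 in the other 5 strains (38.9-fold range, adjusted p = 2.4e-08). Arcn1, a subunit of the coat of Golgi vesicles, read 3.07 ± 0.73 in SvImJ and 6.78 to 7.37 elsewhere (19.7-fold, adjusted p = 5.4e-06). Gas5, a non-coding host of small nucleolar RNAs, split the strains into a low set of SvImJ (5.87 ± 0.22), C3H/HeJ (6.19 ± 0.17) and A/J (6.46 ± 0.14) and a high set from 8.52 ± 0.12 in BALB/cByJ to 9.59 ± 0.06 in C57BL/6J (adjusted p = 7.7e-09). Thumpd1, an RNA-binding protein, was low in A/J, C3H/HeJ, DBA/2J and BALB/cByJ (5.15 to 5.67) and high in the other 4 strains (7.71 to 7.92). Pam, the enzyme that amidates neuropeptides, was highest in SvImJ (7.28 ± 0.29) and DBA/2J (7.11 ± 0.51) and lowest in FVB/NJ (3.30 ± 1.28, adjusted p = 0.0065).

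Other wide ranges among the 25 genes with the largest span were held by Gnb1 and Cap1, low in C57BL/6J, by Irs2, Wnk1, Xrn1 and Grin2b, low in DBA/2J, and by Snhg6 and the probe set of Mir686, high in C57BL/6J. Aldh1a1, which makes retinoic acid, ranged from 5.16 ± 0.47 in BALB/cByJ to 7.79 ± 0.11 in C57BL/6J. Gdpd3, a phospholipase, was high in FVB/NJ (7.09 ± 0.14) and SvImJ (6.86 ± 0.23) and lowest in C57BL/6J (4.14 ± 0.33). Erdr1 was 11.76 ± 0.17 in BALB/cByJ and 11.61 ± 0.15 in SJL/J against 8.79 ± 0.01 in DBA/2J, on a probe set whose suffix marks possible reading of several transcripts. Clip4, Acaa1b and Aldh1a1 had their lowest mean in BALB/cByJ, at 2.71, 3.75 and 5.16. Tbc1d15, Zfp612, Spg21, Ccr6, Itpr2, Ctse and Tcte1 completed the 25, with ranges from 6.04-fold to 9.31-fold.

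In all, limma's moderated F-test called 341 of 7453 probe sets (4.58%) at an adjusted p under 0.05, for 262 named genes. Of these, 294 spanned 2-fold or more and 87 spanned 4-fold or more. With the preparation number as a block the test called 1405 probe sets, all 341 among them, and 760 spanned 2-fold or more. Among the 341, C57BL/6J was the highest strain for 69 and the lowest for 63, BALB/cByJ for 39 and 94, and DBA/2J for 59 and 48.

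**Figure D2:**
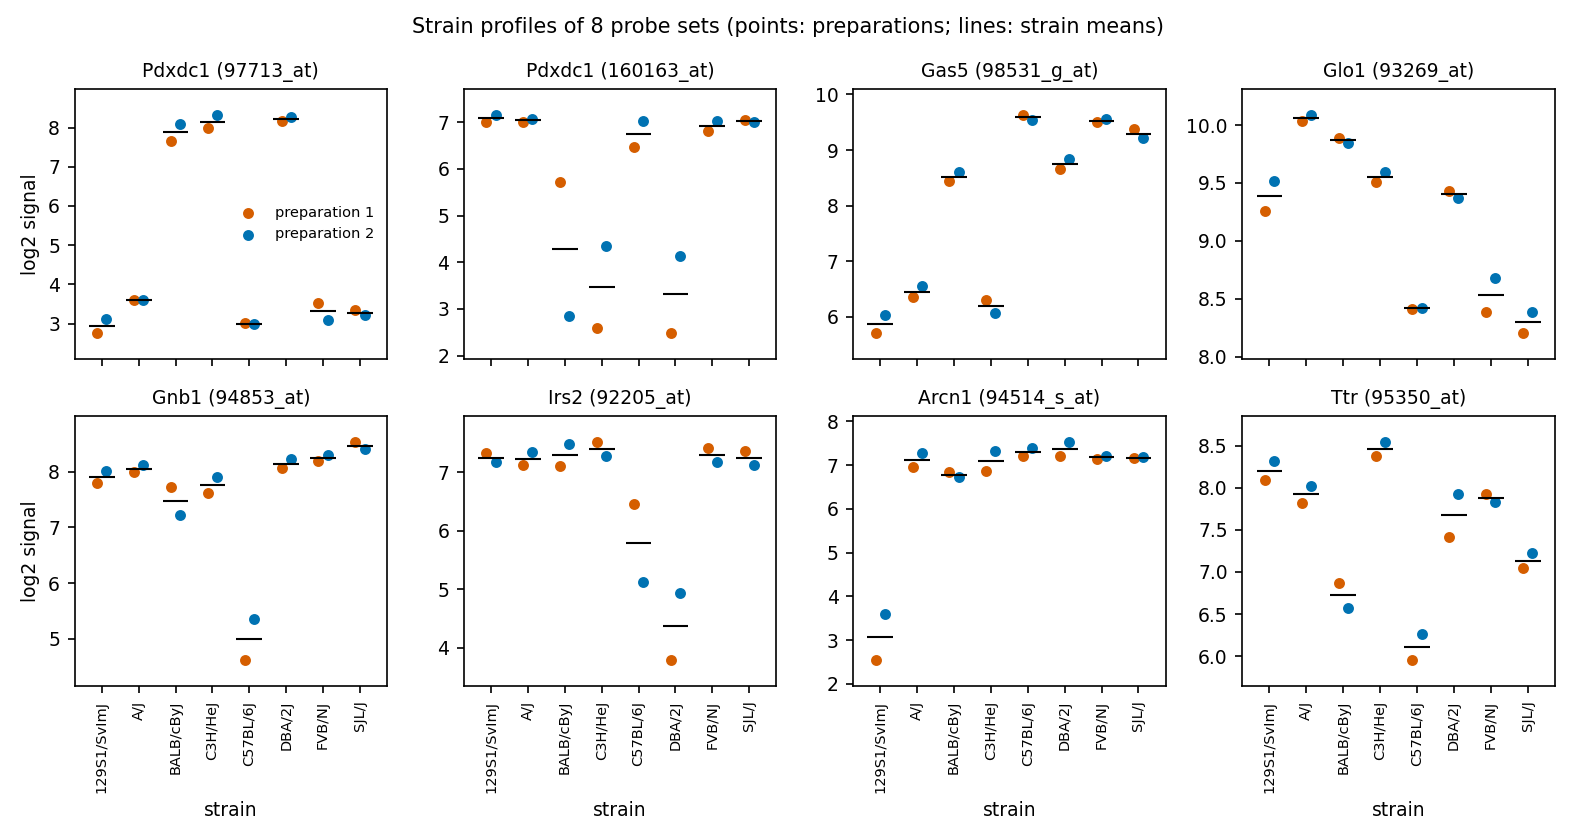
Log2 signal of 8 probe sets in each strain, with a point per cRNA preparation and a line at the strain mean. The first probe set of Pdxdc1 lay at 7.88 to 8.22 in BALB/cByJ, C3H/HeJ and DBA/2J, where the other was lowest, and Arcn1 was low in SvImJ alone among the 8 strains.

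In SvImJ, set against the mean of the other 7 strains, Arcn1 was 16.8-fold lower (log2 difference -4.07 ± 0.22, SE, adjusted p = 1e-07) and Gas5 5.50-fold lower (-2.46 ± 0.12, adjusted p = 9e-08). The DNA damage kinase Atm was also lower (-1.67 ± 0.33, adjusted p = 0.028). Serpina3n, a serine protease inhibitor, was 2.51-fold higher (1.33 ± 0.13, adjusted p = 7.2e-05), and the proteoglycan Spock1 (1.20 ± 0.21) and the cyclin Ccnd2 (1.96 ± 0.41, adjusted p = 0.041) were higher too. The test called 56 probe sets, 26 higher and 30 lower, and 137 with the preparation block. Without preparation 1 or preparation 2 of SvImJ it called 16 or 22.

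A/J was marked by low Hopx, a homeodomain protein of progenitor cells, which was 3.56-fold below the other strains (-1.83 ± 0.17, adjusted p = 8.3e-05). The ribosomal protein gene Rps4l (-1.57 ± 0.18) and Cyp2c38 (-1.75 ± 0.27) were lower as well. The long non-coding RNA Norad was 2.91-fold higher (1.54 ± 0.25, adjusted p = 0.0084), and Mtm1 (1.56 ± 0.30) and the small GTPase Rap2b (1.02 ± 0.17) were higher too. Rap2b had 2 tested probe sets, which correlated at r = -0.187 across strains. Of 40 probe sets past the test, 15 were higher (37.5%) and 25 lower. The share higher was 48.7% with arrays centred on their median. The preparation block gave 99 calls, and leaving out A/J preparation 1 or 2 left 7 or 13.

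With all arrays in the fit BALB/cByJ differed from the rest at more probe sets than any other strain, a rank that C57BL/6J took without BALB/cByJ preparation 1. The lowest among its named genes were Clip4, a microtubule-associated protein (-2.70 ± 0.45, adjusted p = 0.0044), Cpsf3, which cleaves messenger RNA at its end (-1.99 ± 0.24, adjusted p = 0.0004), and Uqcc1, an assembly factor of respiratory complex III (-1.95 ± 0.28, adjusted p = 0.0015). Higher were Gstm5, a glutathione transferase, on 1 of 4 tested probe sets (1.61 ± 0.31, adjusted p = 0.0082), Erdr1 on its second probe set (1.59 ± 0.41) and Prp2 (1.70 ± 0.49, adjusted p = 0.045). That probe set of Gstm5 correlated with its others at -0.857, -0.383 and -0.332 across strains. In total 665 probe sets passed, 232 higher (34.9%) and 433 lower, of which 123 differed by 2-fold or more, and 2267 passed with the preparation block. With arrays centred on their median 1173 passed and 7.4% of them were higher, whereas the share higher was 50.8% with an offset of 64. The mean correlation of an array with its own strain was 0.891 to 0.911 in BALB/cByJ. Outside BALB/cByJ only FVB/NJ array 1 was as low (0.907). The fit gave all strains 1 shared spread at each probe set, so a larger spread in BALB/cByJ would not be counted in full. All 4 arrays of BALB/cByJ were among those with high sense-strand control signal. The days in the titles of its second preparation, whose step the titles do not state, were shared with only 1 array of another strain. The count fell to 117 or 335 without BALB/cByJ preparation 1 or 2, to 303 without FVB/NJ array 2, to 421 without C57BL/6J array 1, to 441 without BALB/cByJ array 2, to 433 without DBA/2J preparation 2 and to 407 without FVB/NJ preparation 2, and it rose to 1202 without BALB/cByJ array 1.

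C3H/HeJ had low Ergic1, a membrane protein between the endoplasmic reticulum and the Golgi (-2.14 ± 0.15, 4.39-fold, adjusted p = 2.5e-06). The imprinted non-coding RNA Meg3 (-1.24 ± 0.12, adjusted p = 0.0001) and the synaptic scaffold Lin7c (-1.56 ± 0.24) were also lower. The value for Meg3 is from 1 of 2 probe sets that passed the F-test, which correlated at r = 0.495 across strains. Transthyretin (Ttr), a transcript abundant in choroid plexus, was 2.12-fold higher (1.08 ± 0.15, adjusted p = 0.0018), as were Srp9 of the signal recognition particle (1.15 ± 0.13) and the growth factor Hbegf (1.10 ± 0.16). The test called 43 probe sets, 20 higher and 23 lower, and 120 with the preparation block. Leaving out preparation 1 of C3H/HeJ left 8 and leaving out its preparation 2 gave 75.

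C57BL/6J had the second largest count. Gnb1, a beta subunit of heterotrimeric G proteins, was 8.07-fold lower (-3.01 ± 0.18, adjusted p = 4.3e-07), and all 3 of its tested probe sets were lowest in this strain. Cap1, a regulator of actin, was 5.73-fold lower (-2.52 ± 0.15) and Ocel1 3.90-fold lower (-1.96 ± 0.17). Higher were the probe set of Mir686 (2.68 ± 0.18, adjusted p = 9.9e-07), Snhg6, a host of small nucleolar RNAs (2.37 ± 0.27), and Prdx2, a peroxiredoxin (1.97 ± 0.19, adjusted p = 3.5e-05). Prdx2 had 2 tested probe sets, which correlated at r = -0.33 across strains. Of 170 probe sets called, 68 were higher (40%) and 102 lower, and with arrays centred on their median the share higher was 62.0%. The preparation block gave 494, and without preparation 1 of C57BL/6J 55 were called.

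DBA/2J was lower than the other strains for Irs2, an adaptor of the insulin receptor (-2.71 ± 0.30, 6.52-fold, adjusted p = 0.00018), for the kinase Wnk1 on 1 of 3 tested probe sets (-2.65 ± 0.36, adjusted p = 0.001) and for the exoribonuclease Xrn1 (-3.26 ± 0.47, adjusted p = 0.0018). The protease cathepsin E (Ctse) was 3.99-fold higher (2.00 ± 0.14, adjusted p = 2e-06). The pericyte transcript Rgs5 (1.74 ± 0.28) and the unnamed locus AI506816 (1.72 ± 0.21) were higher as well. The value for AI506816 is from 1 of 2 probe sets that passed the F-test, which correlated at r = -0.222 across strains. The 107 calls comprised 36 higher and 71 lower, against 318 with the preparation block. Leaving out DBA/2J preparation 1 or 2 left 23 or 43.

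FVB/NJ had the fewest calls without the preparation block, but with it A/J had fewer, at 99. Acad9, which helps assemble respiratory complex I, was 3.77-fold lower (-1.91 ± 0.21, adjusted p = 0.0003), the growth factor Fgf1 3.65-fold lower (-1.87 ± 0.20, adjusted p = 0.00019) and Rnf13 4.01-fold lower (-2.00 ± 0.36, adjusted p = 0.021). The histocompatibility gene H2-D1 on 1 of 2 probe sets (0.87 ± 0.16) and the desaturase Scd1 (0.78 ± 0.15, adjusted p = 0.043) were higher by less than 2-fold. On the other probe set of H2-D1 FVB/NJ read 6.83, and DBA/2J was highest at 7.89. There were 29 calls, 8 higher and 21 lower, and 114 with the preparation block. Either preparation of FVB/NJ left out gave 11.

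SJL/J had low neuronatin (Nnat), an imprinted transcript of neurons (-1.86 ± 0.23, 3.63-fold, adjusted p = 0.0014). Nnt, the mitochondrial transhydrogenase (-1.50 ± 0.23, adjusted p = 0.0063), and Dcaf11 (-1.69 ± 0.32) were lower too. Anp32a (1.18 ± 0.17, adjusted p = 0.0049), Ptov1 (1.17 ± 0.23) and Gnb1 (0.95 ± 0.18) were higher. For Gnb1 the mean of the other strains held the low value of C57BL/6J (4.99). SJL/J read 8.46 against 8.24 in FVB/NJ, the next highest strain for that gene. The test called 41 probe sets, 17 higher (41.5%) and 24 lower, and 30% were higher with arrays centred on their median. With the preparation block 105 were called, and without preparation 1 or 2 of SJL/J 9 or 20.

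**Figure D3:**
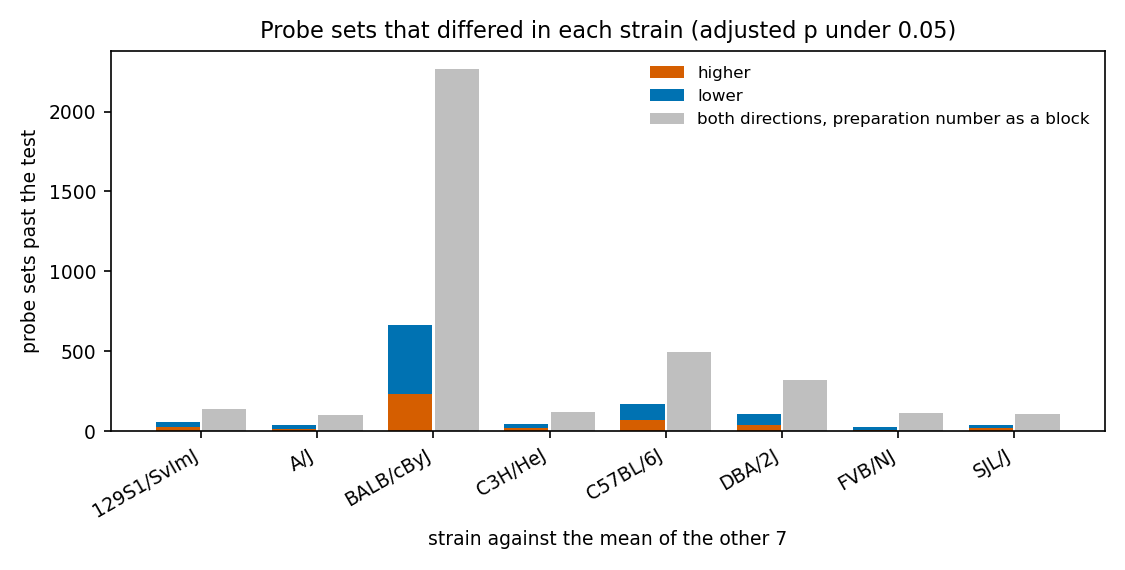
Number of probe sets that differed between each strain and the mean of the other 7, stacked as higher and lower, with the count of the blocked fit in grey. BALB/cByJ had 665 and 2267, C57BL/6J 170 and 494, and FVB/NJ 29 and 114.

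C57BL/6J and DBA/2J are the parents of a widely used panel of recombinant inbred lines, and their direct comparison repeated much of what set each apart. That probe set of Pdxdc1 with the widest range was 37.3-fold lower in C57BL/6J than in DBA/2J (-5.22 ± 0.30, adjusted p = 5e-07), followed by Gnb1 (-3.15 ± 0.23), Cap1 (-2.96 ± 0.20), Pam (-2.76 ± 0.60, adjusted p = 0.044) and Ocel1 (-2.21 ± 0.23). Slc32a1, the vesicular GABA transporter, was 4.70-fold higher in C57BL/6J (2.23 ± 0.22, adjusted p = 7.4e-05). Thumpd1 (2.52 ± 0.25), the probe set of Mir686 (2.45 ± 0.23), Snhg6 (2.22 ± 0.35) and Xrn1 (2.83 ± 0.63, adjusted p = 0.049) were higher too, and Xrn1 lost its call in 37 other settings. The comparison called 72 probe sets, 42 higher and 30 lower in C57BL/6J, 60 of them by 2-fold or more, and 152 with the preparation block. It called 36 without C57BL/6J preparation 1, and 30 or 39 without DBA/2J preparation 1 or 2.

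Across the 28 pairs of strains the median number of probe sets that passed and differed by 2-fold or more was 67. FVB/NJ and SJL/J were the closest pair, with 21, and BALB/cByJ and C57BL/6J the farthest, with 271. With the preparation block the median was 120 and the pairs ranged from 38 to 537. Leaving out DBA/2J preparation 1 brought the median to 41.5.

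Among genes of synaptic transmission, few or none of the members of each group passed the F-test, and more did with the preparation block. Of 11 tested glutamate receptor genes, 1 passed the F-test (2 adjusted over the list alone): Grin2b, an NMDA receptor subunit, read 4.73 ± 0.59 in DBA/2J and 6.5 to 7.36 in the other strains (adjusted p = 0.00026). Of 10 genes of GABA synthesis, transport and reception, 2 passed (4 adjusted over the list alone). Slc32a1 was low in DBA/2J (6.89 ± 0.30 against 8.68 to 9.12), and the receptor subunit Gabra2 was low in C57BL/6J (6.53 ± 0.28 against 8.00 to 8.62). Of 25 vesicle and release genes, 2 passed (3 over the list alone). Cplx2, a complexin of the release machinery, ranged from 8.24 ± 0.31 in DBA/2J to 10.65 ± 0.26 in A/J, and the calcium sensor Syt1 from 9.19 ± 0.15 in BALB/cByJ to 10.36 ± 0.03 in DBA/2J. Of 33 plasticity genes, 4 passed (6 over the list alone): the kinase Camk2a, the phosphodiesterase Pde1a and the neurotrophin receptor Ntrk2 were lowest in DBA/2J, and neurogranin (Nrgn) was lowest in SJL/J. Of 30 voltage-gated and related channel genes, 3 passed (4 over the list alone). On 1 of 2 tested probe sets Kcnj9, a G-protein-gated potassium channel, read 6.57 ± 0.09 in C57BL/6J and 7.69 to 8.34 in the other strains (adjusted p = 0.00081). Its other probe set did not pass and correlated with the first at r = -0.351. Kcnma1 and Kcnab2 were highest in C57BL/6J. None of 19 monoamine and acetylcholine genes and none of 20 immediate early genes passed limma's test over all genes or over the list alone, and 3 of each passed with the preparation block.

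Among genes of metabolism and immunity, Glo1, the glyoxalase that clears methylglyoxal, had the clearest pattern. On 1 of 2 probe sets it was 10.06 ± 0.04 in A/J, 9.87 ± 0.03 in BALB/cByJ and 9.39 to 9.55 in C3H/HeJ, DBA/2J and SvImJ, against 8.30 to 8.53 in C57BL/6J, FVB/NJ and SJL/J (adjusted p = 7.3e-06), and the other gave the same division of the strains. Glo1, Nnt, Mgst3 and Prdx3 were the 4 of 35 antioxidant genes that passed (6 over the list alone). Of 57 respiratory chain genes 5 passed (7 over the list alone), and Ndufa7, Ndufc1 and Sdhc were lowest in BALB/cByJ and Cox6c in SvImJ. Of 17 genes of antigen presentation 2 passed (4 over the list alone): 1 probe set each of H2-D1 and H2-K1 was highest in DBA/2J (7.89 ± 0.30 and 7.80 ± 0.14) and lowest in C3H/HeJ (6.06 ± 0.04 and 6.53 ± 0.05), on probe sets that may read several related transcripts. The other tested probe set of H2-K1 did not pass and correlated with that one at r = -0.422 across strains. Ly6e was 1 of 7 interferon response genes to pass (1 over the list alone). Its other tested probe set did not pass and correlated with the passing one at r = -0.461 across strains. Of 23 neuropeptide genes 1 passed (2 over the list alone), Penk, with 6.92 ± 0.07 in A/J and 8.27 ± 0.27 in DBA/2J.

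Markers of cell types and of neighbouring tissue also differed. Ttr passed as 1 of 5 choroid plexus markers (3 over the list alone), from 6.11 ± 0.22 in C57BL/6J to 8.46 ± 0.12 in C3H/HeJ (adjusted p = 4.8e-05). The haemoglobin genes Hbb-b2 and Hba-a1 passed, 2 of 3 blood cell markers (2 over the list alone), and both were highest in C3H/HeJ (7.92 ± 0.26 and 10.39 ± 0.12). Mag was 1 of 14 myelin markers to pass (2 over the list alone) and was highest in C57BL/6J (8.31 ± 0.19). The other tested probe set of Mag did not pass and correlated with that one at r = -0.22 across strains. Fabp7 and Ntsr2 were 2 of 20 astrocyte markers (5 over the list alone), Ctss 1 of 11 microglial markers (4 over the list alone) and Rgs5 1 of 10 vascular markers (1 over the list alone). Nnat and Neurod1 were 2 of 16 principal neuron markers (6 over the list alone), Slc32a1 1 of 15 interneuron markers (2 over the list alone) and Penk 1 of 9 markers of neighbouring regions (1 over the list alone). The share of called genes was above the 232 of 5660 (4.1%) among all genes in every list but monoamine and acetylcholine genes and immediate early genes. It was 12.1% for plasticity genes and 8.8% for the respiratory chain. No list passed after adjustment over 21 lists (two-sided Fisher's exact test, lowest adjusted p = 0.102, for blood cell markers, and 2 lists at an unadjusted p under 0.05). With 3 to 57 tested genes in a list the test had little power, so an excess is not excluded. With the preparation block the number of called genes rose by more than 1.5 times in 18 lists, to 18 in the respiratory chain and 11 each in plasticity and channels.

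Tested as whole lists in each strain with limma's camera, 12 of 168 list and strain pairs passed, none of them with a correlation estimated from the data, and 11 with the preparation block. In DBA/2J, glutamate receptor genes lay lower as a group (median log2 difference -0.26, 8 of 11 lower, adjusted p = 0.0128, adjusted p = 0.205 with an estimated correlation), as did plasticity genes (median -0.04, 20 of 33 lower, adjusted p = 0.0279, adjusted p = 0.205 with an estimated correlation). In SvImJ plasticity genes lay higher (median 0.13, 25 of 33 higher, adjusted p = 0.0237) and so did choroid plexus markers (median 0.48, 4 of 5 higher, adjusted p = 0.0103), both with adjusted p = 0.205 with an estimated correlation. In C57BL/6J choroid plexus markers were lower (median -0.53, 5 of 5 lower, adjusted p = 0.00127, adjusted p = 0.205 with an estimated correlation), myelin markers higher (median 0.25, 10 of 14 higher, adjusted p = 0.0279, adjusted p = 0.223 with an estimated correlation) and respiratory chain genes higher (median 0.09, 40 of 57 higher, adjusted p = 0.0264, adjusted p = 0.424 with an estimated correlation). In C3H/HeJ the 3 blood cell markers were higher (median 0.92, adjusted p = 0.000497, adjusted p = 0.205 with an estimated correlation), respiratory chain genes higher (median 0.12, 40 of 57 higher, adjusted p = 0.00649, adjusted p = 0.355 with an estimated correlation) and myelin markers lower (median -0.15, 13 of 14 lower, adjusted p = 0.0279, adjusted p = 0.223 with an estimated correlation). In A/J respiratory chain genes were higher (median 0.08, 43 of 57 higher, adjusted p = 0.0103, adjusted p = 0.358 with an estimated correlation) and markers of neighbouring regions lower (median -0.18, 8 of 9 lower, adjusted p = 0.0355, adjusted p = 0.258 with an estimated correlation), a call that the preparation block ended (adjusted p = 0.0976).

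A list of 17 tested genes, fixed beforehand because strain differences are known or plausible for them, is not independent evidence, since some of that knowledge may come from these same strains. Of the 17, 8 passed the F-test (9 adjusted over the list alone): Glo1, Kcnj9, Gabra2, Nnt, Gas5, Pttg1, Ttr and Pam. Pttg1, known as securin, was 8.28 ± 0.32 in C57BL/6J and 6.34 to 6.87 in the other strains (adjusted p = 0.0012). The complement regulator Cd59a ranged from 4.76 to 6.16 (adjusted p = 0.053), and Gsr, Psph, Apoe, Ide, St8sia4, Ndn, Rab4a and Lxn had adjusted p between 0.41 and 0.97. Apoe ranged from 12.18 in DBA/2J to 12.58 in C3H/HeJ. The X-inactivation transcript Xist was below the signal filter in every strain, at 3.41 or less, and the Y-linked Eif2s3y read 5.64 to 6.55 (adjusted p = 0.70). The Y-linked Kdm5d (2.43 to 3.07) and Uty (2.67 to 4.81) were left out by the filter. The probe set of Eif2s3y may read several transcripts, so these values do not settle the sex of the mice.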

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

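The test of FVB/NJ array 1 against the BALB/cByJ pattern, the test of FVB/NJ array 2 and the test of the direction of C57BL/6J calls were chosen after the result was seen. In groups of 4 arrays, chance places 1 array far from the others in about 1 group of 20. Here 11 of 236 groups had such an array, against 11.8 that chance gives.

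FVB/NJ array 1 stood apart from the other 3 arrays of its strain on 2 measures: its score on the first component of variation within strains was -33.76 against 10.37 to 12.71, and its mean correlation with its own strain was 0.91 against 0.95. C57BL/6J array 2 had a mean correlation of 0.93 with its own strain against 0.95. Single arrays were also far from the rest for Zfp612 (2.46 in C57BL/6J array 1 against 3.90 to 4.15), Spg21 (6.33 in FVB/NJ array 1 against 7.31 to 7.43) and Itpr2 (5.40 in C57BL/6J array 4 against 2.85 to 3.00). The same held for Cyp2c38 (4.95 in A/J array 3 against 3.50 to 3.71), Ocel1 (4.47 in C57BL/6J array 3 against 4.90 to 4.94) and H2-K1 (6.42 in C3H/HeJ array 3 against 6.56 to 6.57). The last 2 were Ctss (8.89 in A/J array 3 against 8.76 to 8.78) and St8sia4 (5.26 in FVB/NJ array 1 against 6.37 to 6.53). Outside the main measurement, the sense-strand control probe sets read 6.95 or more on 11 arrays and 5.64 or less on the other 21.

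BALB/cByJ had 665 calls against the rest. Whether sense-strand target in the cRNA was the cause could not be decided. An effect estimated from the preparations of 6 other strains had the sign of the BALB/cByJ difference in 55% of its calls (95% exact interval 51.2% to 58.9%). Its median size there was 0.14 against 0.74 for the BALB/cByJ difference, at probe sets selected for that difference. The 3 estimates behind it, each from 1 pair of strains, correlated at only -0.0411 to 0.0988. Its sign was thus mostly noise, and the test cannot decide. In the blocked fit, the sense-strand control signal as a covariate left 159 higher and 238 lower calls, from 1032 and 1235. That signal was high on all 4 BALB/cByJ arrays, so the covariate overlapped with the strain and the drop cannot decide either. Calls also fell in C57BL/6J, from 225 higher and 269 lower to 104 and 143, but little in C3H/HeJ, from 58 and 62 to 53 and 55. Leaving out any 1 of the 4 BALB/cByJ arrays left 441 calls or more (66.3% of 665), so the count did not rest on 1 array alone. It still moved with single arrays, to 441 without array 2 and 1202 without array 1. BALB/cByJ array 2 scored -36.56 on the second component of variation within strains, where all other arrays lay between -8.18 and 20.46. A contribution of that array thus stays open. A shift of arrays remains open. The departure of FVB/NJ array 1 from its strain was taken less that of same-numbered arrays of the other strains outside BALB/cByJ. It had the sign of the BALB/cByJ difference at 80.8% of the probe sets called in BALB/cByJ (77.5% to 83.7%). Both intervals in this paragraph take probe sets of the same arrays as independent, so they are too narrow and do not measure spread between arrays. The other 27 arrays outside BALB/cByJ ranged from 17.7% to 62.7%. The lowest was FVB/NJ array 2. Part of the BALB/cByJ count may therefore be technical, and a difference of the strain itself stays open beside it.

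FVB/NJ array 2 sat with preparation 2 on the first component (12.7, where arrays 1 and 2 of the other 7 strains lay at or below -3.88). Its sense-strand control signal was 5.329, close to arrays 3 and 4 (5.09 and 5.62) and far from array 1 (7.39), and its title gives the same day as that of array 3 of 6 other strains. A candidate explanation is that array 2 carries cRNA of the second preparation. Counted so, the strain effect of BALB/cByJ moved to 313 calls. An array 1 that is itself unusual stays open, and no biological explanation applies within 1 pool.

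Chance was weighed for each count with 100 regroupings of the 16 preparation values into 8 pairs, the real one included. For the 341 and 294 probe sets across strains 1 regrouping gave as many, the real one, and the highest other gave 139 and 131. The median over pairs was 67 and the highest other 18 (1 of 100). The real value was reached by 2 of 100 for SvImJ (56, highest other 558), 3 for A/J (40, 559), 1 for BALB/cByJ (665, 65), 2 for C3H/HeJ (43, 57), 3 for C57BL/6J (170, 996), 3 for DBA/2J (107, 397), 3 for FVB/NJ (29, 206) and 2 for SJL/J (41, 633). Between C57BL/6J and DBA/2J 4 of 100 gave the 72 calls, with 209 as the highest other. For each of the 12 counts that share lay under 0.05, with no adjustment over the 12. The 2 values of a strain come from 1 pool, so this weighs technical spread and not differences between animals. These regroupings also do not keep 1 value of each preparation in every group. The regroupings with several times the real count point to a structure of the samples: those with 558, 559, 996 and 397 put both BALB/cByJ preparations in 1 group, and those with 206 and 633 paired the first preparations of BALB/cByJ and C3H/HeJ. Among 50 regroupings that keep 1 value of each preparation in every group, as the real one does, the highest other F-test count was 29 without the block against 341, and 58 with it against 1405. The counts per strain and per pair were not taken for these.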

How the results depend on the processing

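The alternatives with the sense-strand control signal and those that move array 2 of FVB/NJ were chosen after the data were seen. Series of counts below run in this order: probe sets that differ between strains, those by 2-fold or more, then SvImJ, A/J, BALB/cByJ, C3H/HeJ, C57BL/6J, DBA/2J, FVB/NJ and SJL/J against the rest, the median over pairs, and C57BL/6J against DBA/2J. As reported they were 341, 294, 56, 40, 665, 43, 170, 107, 29, 41, 67 and 72. Under quantile normalization, no filter, the filter at the highest 40% and an offset of 16, all 12 counts stayed within 1.5 times of these.

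The preparation number as a replicate block gave 1405, 760, 137, 99, 2267, 120, 494, 318, 114, 105, 120 and 152, and every one of the 341 probe sets was called there too. Single arrays with the array number as a replicate block gave 2465, 956, 213, 202, 2721, 242, 794, 592, 225, 193, 133 and 244. Single arrays with the day as a term and a correlation within preparations gave 2003, 837, 238, 239, 1687, 252, 838, 730, 145, 222, 132.5 and 266, and taken as independent they gave 1388, 686, 151, 128, 2048, 146, 549, 305, 104, 128, 118 and 174. These fits on single arrays all treat hybridisations as replicates, at least in part. With only the correlation within preparations the counts that moved were 667, then 95, 72, 1078, 84, 279, 176, 63 and 70 for the strains, and 111 for C57BL/6J against DBA/2J. The block together with the sense-strand control signal as a covariate gave 617 and 466, with 74 for A/J, 397 for BALB/cByJ, 108 for C3H/HeJ, 174 for DBA/2J, 106 for FVB/NJ and 108 for SJL/J, a pair median of 101.5 and 141 for C57BL/6J against DBA/2J.

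With FVB/NJ array 2 counted with preparation 2, BALB/cByJ had 313 calls and the other counts stayed within 1.5 times. The same with the preparation block gave 1003, 600, 113, 74, 1847, 87, 403, 270, 74, 90, 115 and 125. Without the 11 arrays of high sense-strand control signal, which removes BALB/cByJ, the counts that moved were 162 and 159, with 10 for A/J, 15 for C3H/HeJ, 7 for SJL/J and a pair median of 31. Leaving out BALB/cByJ and FVB/NJ gave 207 and 190. An offset of 64 compresses low signals and gave 161 probe sets by 2-fold or more and a pair median of 29. Variances without a trend gave 35 for SvImJ, 19 for FVB/NJ and 24 for SJL/J. Arrays centred on their median gave 1173 for BALB/cByJ. That centring moved the median of all tested probe sets by -0.15 in BALB/cByJ and 0.10 in C57BL/6J relative to the rest, and leaving out the filter moved it by 0.16 in BALB/cByJ. Changes in single genes are larger than these shifts. Apart from fewer values or arrays in some settings, the cause was not tested.

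Each array and each preparation was left out in turn, and a lone preparation was assumed to vary like those of the other strains. Counts then ranged from 260 to 380 probe sets, 237 to 330 by 2-fold or more, 16 to 60 for SvImJ, 7 to 47 for A/J, 117 to 1202 for BALB/cByJ, 8 to 75 for C3H/HeJ, 55 to 219 for C57BL/6J, 23 to 125 for DBA/2J, 11 to 34 for FVB/NJ, 9 to 49 for SJL/J, 41.5 to 75.5 for pairs and 30 to 80 for C57BL/6J against DBA/2J. The omissions that moved a count by over 1.5 times stand beside that count in the report. Leaving out single arrays moved only the count of BALB/cByJ that far, without its arrays 1 (1202) and 2 (441), C57BL/6J array 1 (421) and FVB/NJ array 2 (303).

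Among named differences of a strain from the rest or between C57BL/6J and DBA/2J, none changed direction under any alternative. These genes were picked for large differences, so a change was unlikely from the start, and a range across strains has no direction. Of 2157 combinations of a named gene result with an alternative other than leaving out, 2024 kept their side of the threshold, 114 lost the call and 19 gained one, and of 6240 with an array or preparation left out 5943 kept it. The calls lost most often were Xrn1 between C57BL/6J and DBA/2J (37 settings), Prp2 in BALB/cByJ (29), Scd1 in FVB/NJ (28), Ccnd2 in SvImJ (27) and Pam between C57BL/6J and DBA/2J (24). For whole lists, 0 passed Fisher's exact test under each of the 4 alternatives run, and camera called 12 pairs as reported, 9 under quantile normalization, 11 with the preparation block and 0 with an estimated correlation. The median share of variance of strain was 8.67% under quantile normalization and 4.52% without a filter. With no detection calls, signals near the limit of the filter cannot be told from background.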

Other observations

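The tests in this part on probe sets of 1 gene and on neighbouring genes were planned before their results were seen, apart from that on C57BL/6J calls. The genes named here were chosen after their values were seen. Casp9, an initiator of apoptosis, was read by 4 probe sets that all passed the F-test and were all high in BALB/cByJ and C3H/HeJ: on 1 of them it was 6.99 ± 0.38 and 6.95 ± 0.33 there (SD, n = 2) against 4.58 to 5.17 in the other 6 strains. Lipoprotein lipase (Lpl) was lowest in C57BL/6J on both of its probe sets, at 5.59 ± 0.35 and 4.29 ± 0.54. Ptgds, a prostaglandin D synthase of meninges and choroid plexus, was highest or next to highest in SvImJ on 3 probe sets (10.51, 10.23 and 10.26) and lowest in A/J (9.14, 8.67 and 8.70). A further set of genes was low in both C57BL/6J and DBA/2J. On 1 of 2 passing probe sets each, Dusp8 read 6.08 ± 0.23 and 6.59 ± 0.13 there against 7.86 to 8.21 elsewhere, Rab10 read 6.64 ± 0.27 and 6.80 ± 0.20 against 7.55 to 8.46, and Wnk1 read 4.36 ± 0.54 and 3.94 ± 0.40 against 5.98 to 6.36. The remaining tested probe set of Wnk1 did not pass and correlated with the 2 that did at r = -0.311 and -0.092 across strains.

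Some genes had probe sets with opposite strain profiles. The widest-ranging probe set of Pdxdc1 was high in BALB/cByJ, C3H/HeJ and DBA/2J, where its other 2 (4.45 to 4.94, and 3.32 to 4.29) were low, with 6.44 to 7.08 and 6.75 to 7.08 in the other 5 strains. For tau (Mapt), 1 probe set was highest in C57BL/6J (9.91 ± 0.38) and another lowest in DBA/2J (8.08 ± 0.02). Probe sets that read a sequence variant or a transcript form rather than the amount could give such profiles. Of 34 pairs of probe sets of 1 gene that both passed, 4 (11.8%) had a correlation under 0 across strains and 25 had one over 0.8, a share between the limits of 5% and 20% set for this test, so that the explanation cannot be told apart from differences in amount for the genes as a set. Where 1 of the 2 probe sets passed, 39.1% of 87 pairs had a correlation under 0, and where neither did, 32% of 1127. If probes matched the C57BL/6J sequence best, its calls should mostly be higher. Of its calls 40% were (upper limit of the 95% exact interval 47.8%, with probe sets taken as independent), but 62% were with arrays centred on their median. The direction thus turned on the scaling, and the test does not decide on that form of the explanation.

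Genes with strain differences lay next to each other more often than chance gives. Among 5651 tested genes in chromosomal order 232 had passed the F-test, and 18 of them had a passing gene as their next tested neighbour, against a median of 9 in 10000 random draws (central 95% 4 to 16, one-sided permutation p = 0.0059). Pairs included Acaa1b and Acaa1a (r = 0.859 across strains), Neurod1 and Pde1a (0.877), H2-K2 and H2-K1 (0.624), Nbl1 and Micos10 (-0.928) and Mgst3 and Rgs5 (0.408). Shared inherited segments may contribute to this, as may probe sets that read related neighbours such as the Acaa1 and H2 pairs, and the 18 pairs do not separate the 2.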
